A study of Arabidopsis thaliana with 2 samples.

How the data were processed

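Binding of purified protein complexes to Arabidopsis thaliana genomic DNA was measured by sequential DNA affinity purification sequencing, in which proteins made outside the plant are mixed with fragmented genomic DNA and the bound fragments are sequenced. Per the labels, the DNA came from untreated 2-week-old seedlings, and 2 complexes of the MADS-domain proteins SEPALLATA3 (SEP3) and AGAMOUS (AG) were measured, both described as altered in tetramer formation. They are named here as in the sample titles: SEP3Δtet3M-AG and SEP3Δtet-AGΔtet. The genotype label of both samples reads SEP3Δtet3M-AG, so the groups were taken from the titles, which match the pair of complexes named in the series' design text. The labels do not explain what 3M stands for, and no meaning is assumed here. The unaltered SEP3-AG complex and the earlier mutant SEP3ΔtAG, which the design text also names, were not analysed here.

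The deposited files hold peak positions: a chromosome, a start and an end, in 3 columns with no header, and every peak in both files is 400 bp wide. The submitters' processing notes name Bowtie2, SAMtools and MACS2, without versions. The caller's settings, the genome build, the number of reads and whether libraries were pooled before calling are not given in the sources used here. The files used here carry no score, fold, p-value or summit, so a peak counts as present or absent and its midpoint stands for its summit. The depth behind each list is unknown, and each complex has 1 list, so no replicate error could be estimated. Intervals below are exact 95% Clopper-Pearson intervals unless stated otherwise, and they cover the counting of peaks or genes only. Peaks and genes are not replicate libraries, so each test describes these 2 lists and does not test a difference between the complexes.

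Genes were taken from the TAIR10.1 RefSeq gene table, with 27444 protein-coding genes on chromosomes 1 to 5 and 37899 genes of every type. The table holds gene starts and ends without strand, exons or untranslated regions, so upstream and downstream sides are not separated and no peak is assigned to an exon or an intron. Because the build of the peak files is not named, their fit to this table was checked by moving all peaks together by 200 to 20000 bp in either direction and recording the share of midpoints inside protein-coding genes. Only peak coordinates, counted from 1, are printed. Gene coordinates are not.

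The following choices were made before the data were examined: the groups, the overlap test, 5 gene lists with 138 members, the comparisons with random placement, and the rule for naming genes. All 138 list members were found in the gene table by locus identifier. A peak of 1 list was called shared when it had at least 1 bp in common with a peak of the other. The number shared was set against 1000 random placements of the other list on the same chromosomes, from the chromosome's start to its last gene or peak (one-sided permutation test, for which 0.001 is the smallest p that 1000 placements can give). A gene was counted as having a peak when a midpoint lay inside it or within 3000 bp on either side. The plan had allowed 1000 bp downstream, which needs the strand. Each list was set against all other protein-coding genes by Fisher's exact test (two-sided), with Benjamini-Hochberg adjustment over 10 tests, and against 1000 random placements of the peaks (two-sided permutation test, with 0.002 as the smallest p). Peak location (inside a gene, outside but within 1000 bp of one, or farther away) was compared with 10 random positions per peak on the same chromosome by Fisher's exact test, adjusted over 6 tests. The plan had asked for the upstream side only and for background positions matched for GC content. Low-gene windows are 500 kb windows with fewer than 0.5 times the chromosome's median number of protein-coding genes, and the share of peaks in them was set against 1000 random placements.

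Some comparisons were chosen after the data were seen. These are the location of peaks found in 1 list only (Fisher's exact test, adjusted over 9 tests, with normal-approximation intervals for differences of shares), the exact binomial test of genes with a peak in 1 list only, the share of list-gene peaks that were shared, gene families defined by their names, microRNA genes and neighbouring peaks. That binomial test takes an equal split between the lists unless stated otherwise. Of all protein-coding genes with a peak in 1 list only, 67.9% fall to the longer SEP3Δtet-AGΔtet list. Alternatives planned beforehand were merged peaks, 200 bp of overlap, midpoints within 100 bp, gene flanks of 1000 or 3000 bp, random placement, peaks outside low-gene windows, and windows of 200 kb. Added later were joint shifts of all peaks of a chromosome, random placement keeping the numbers inside, next to and far from genes, shared peaks alone, peaks found with 1 complex alone (for the gene lists, with that same placement), gene lists without low-gene windows, and genes of every type.

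Genes were to be named by 3 rules. The first takes every list gene with a peak in its territory in either list, up to 30 by fold. The other rules rank peaks by fold, which the files used here do not hold, so they could not be applied, nor could the limit of 30. All 52 list genes with a peak were therefore eligible, and not every one of them is reported here by name. Other genes named in the closing section were chosen after their values were seen. Planned searches for CArG boxes, for pairs of such boxes and for enriched 6-mers, and the GC-matched background, need a genome sequence, which was not used here. Planned comparisons of fold enrichment and of the stricter part of each list need a score and were not run.

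The calculations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3, and the plots were drawn with Matplotlib 3.10.9. The steps were tested on simulated data. Of 200 peaks planted as shared, a mean of 197 was found above the number without planting. Lists of 40 genes, of which 15 were given a peak, passed the threshold in 100 of 100 simulations, and lists without planted peaks passed it in 6 of 100. Random peak lists passed the location test in 4 of 100 simulations.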

Results

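DNA regions bound by the SEP3Δtet3M-AG and SEP3Δtet-AGΔtet complexes were compared, with 1 peak list per complex. SEP3 and AG are MADS-domain transcription factors that specify the inner organs of the flower, and they can join into a tetramer that holds a pair of DNA elements. The series' design text asks how complexes altered in tetramer formation bind DNA. The list for SEP3Δtet3M-AG held 1681 peaks covering 671411 bp, and that for SEP3Δtet-AGΔtet held 2277 peaks covering 910584 bp, 1.355 times as many peaks. With no replicate and an unknown depth, this difference in number has no test. Peaks lay on all 5 nuclear chromosomes and none on an organelle chromosome. Their density ranged from 13.5 to 14.8 per Mb across chromosomes for SEP3Δtet3M-AG and from 18.5 to 19.9 per Mb for SEP3Δtet-AGΔtet.

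MADS-box genes themselves carried peaks more often than other protein-coding genes with both complexes. Of the 34 MADS-box genes in the fixed list, 17 had a peak within 3000 bp with SEP3Δtet3M-AG (50%, 95% interval 32.4 to 67.6), against 12% of other genes. The same number, 17, had one with SEP3Δtet-AGΔtet, against 15.8% of other genes. Fisher's exact test gave an odds ratio of 7.34 (adjusted p = 6.92e-07) for the former and 5.34 (adjusted p = 1.79e-05) for the latter. With random placement of the peaks, a mean of 4.34 and 5.73 list genes had a peak (two-sided permutation p = 0.002, the smallest possible, and adjusted p = 0.01 for each). Peaks found with 1 complex only lay near 5 of the 34 genes in each list (14.7%) and did not pass. Random placement matched for position gave 4.52% for SEP3Δtet3M-AG (permutation p = 0.05, adjusted p = 0.25) and 9.04% for SEP3Δtet-AGΔtet (permutation p = 0.39, adjusted p = 1).

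Both lists held a peak at 13 MADS-box genes, among them regulators of floral organs and of flowering time. AG had a peak inside the gene in both lists, at chromosome 4, 10386353 to 10386752 with SEP3Δtet3M-AG, and the SEP3Δtet-AGΔtet peak lay 10 bp away. A further peak of each list, at 10381096 to 10381495 with SEP3Δtet3M-AG, lay within 3000 bp of AG. AP3, which specifies petals and stamens, had a peak inside the gene in both lists (chromosome 3, 20121047 to 20121446 with SEP3Δtet3M-AG), with midpoints 6 bp apart. The ovule and fruit regulators SHP2 and STK each had a peak in both lists, although the gene nearest to the STK peak was AT4G09950. Among regulators of the floral transition, SOC1 had 2 peaks in each list, 1 of them within 1000 bp of the gene (chromosome 2, 18810952 to 18811351 with SEP3Δtet3M-AG). SVP, a repressor of flowering, and AGL24, a promoter of it, had peaks inside the gene in both lists. AGL14, AGL16, AGL17, AGL18, AGL19 and AGL21 complete the group, and the peaks inside AGL19 (chromosome 4, 12026412 to 12026811 with SEP3Δtet3M-AG) lay 2 bp apart.

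Other MADS-box genes had a peak in 1 list only. The meristem identity genes AP1 and CAL had a peak inside the gene with SEP3Δtet3M-AG alone. In the same list alone, SEP4 had a peak within 1000 bp and PI, the partner of AP3, within 3000 bp. FUL, a fruit and meristem regulator, had a peak inside the gene with SEP3Δtet-AGΔtet alone (chromosome 5, 24504866 to 24505265). AGL15, TT16 and SEP3 had peaks near them in that list alone. The gene nearest to the peak was DIN10 for PI and AT1G24265 for SEP3. With 4 genes in each list only, no difference between the lists in the number of MADS-box genes was detected (exact binomial p = 1). None was detected against the split of all genes with a peak in 1 list only either (exact binomial p = 0.2797). Of the 22 SEP3Δtet3M-AG peaks at MADS-box genes, 12 lay inside the gene, 5 within 1000 bp and 5 farther away. Of the 23 SEP3Δtet-AGΔtet peaks there, the numbers were 11, 7 and 5. In the latter list 73.9% of the peaks at MADS-box genes were shared, against 49.4% of its other peaks (Fisher's exact p = 0.0212), a difference that did not pass after adjustment over the lists (adjusted p = 0.212).

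**Figure D1:**
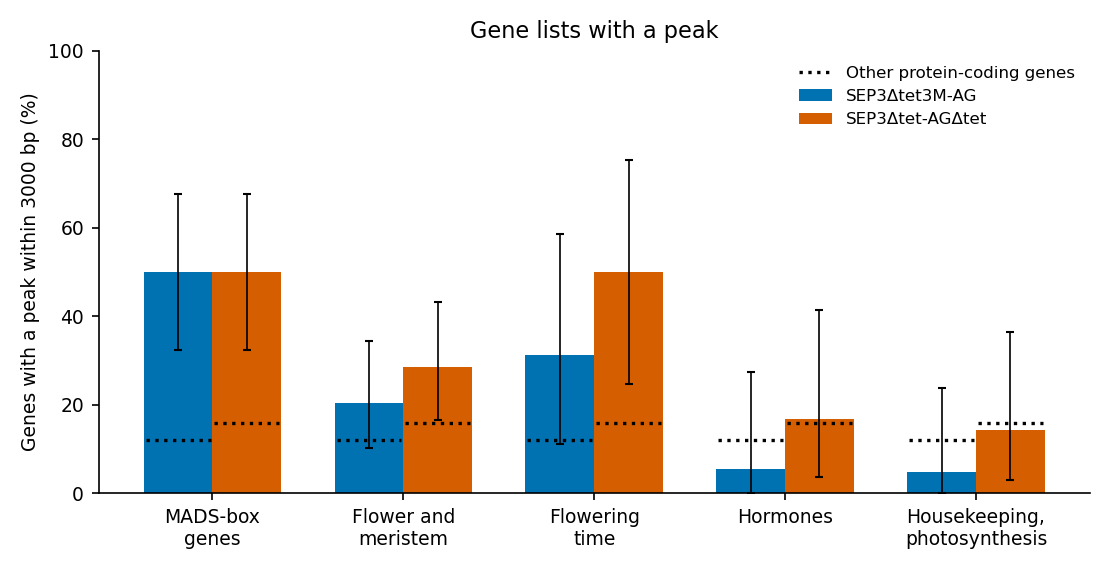
Share of the genes in each fixed list with a peak midpoint inside the gene or within 3000 bp, in percent, for the SEP3Δtet3M-AG list (blue) and the SEP3Δtet-AGΔtet list (orange). Bars show 1 library each, error bars are exact 95% binomial intervals over genes, and dotted lines mark all other protein-coding genes; MADS-box genes stand at 50% in both lists, against 12% and 15.8% of other genes.

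Flowering-time genes carried peaks more often than other genes with SEP3Δtet-AGΔtet. Of the 16 genes in the list, 8 had a peak there (50%, interval 24.6 to 75.4), against 15.8% of other genes (odds ratio 5.33, Fisher's exact adjusted p = 0.00501). With SEP3Δtet3M-AG, 5 had one (31.2%, interval 11.02 to 58.7), which did not pass (Fisher's exact adjusted p = 0.0705). SMZ, SNZ, TOE1 and TOE3, AP2-family repressors of flowering, had a peak in both lists. FT, which encodes the mobile flowering signal, had a peak inside the gene with SEP3Δtet3M-AG alone (chromosome 1, 24331588 to 24331987). TEM1 and TEM2, repressors of FT, and FD and SPL5 had peaks with SEP3Δtet-AGΔtet alone. Another gene lay nearest to the peak at TEM2 (STN7), FD (LARP1c) and SPL5 (AT3G15280) and, in both lists, at SMZ (TON1A) and SNZ (AT2G39260). The numbers in 1 list only, 1 and 4, were too few to show a difference from an equal split between the lists (exact binomial p = 0.375). They did not differ detectably from the split of all genes with a peak in 1 list only either. Of the 9 SEP3Δtet-AGΔtet peaks at flowering-time genes, 6 lay over 1000 bp from the gene, and the list gene was the nearest gene for 4. At a limit of 1000 bp only TOE1 and SNZ remained with that complex (12.5%, Fisher's exact adjusted p = 0.741). The call was also lost with shared peaks only (25% against 8.37%, Fisher's exact adjusted p = 0.0989) and with peaks found with SEP3Δtet-AGΔtet only (31.2% against a random 8.46%, permutation p = 0.026, adjusted p = 0.25).

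Genes of flower and meristem development did not pass the test after adjustment with either complex. With SEP3Δtet3M-AG, 10 of 49 had a peak (20.4%, interval 10.2 to 34.3; Fisher's exact adjusted p = 0.131), and with SEP3Δtet-AGΔtet 14 did (28.6%, interval 16.6 to 43.3; adjusted p = 0.0703). SUP, which sets the boundary between stamens and carpels, had 2 peaks in each list, and those within 1000 bp of it had midpoints 1 bp apart (chromosome 3, 8241150 to 8241549 with SEP3Δtet3M-AG). MYB21, a regulator of stamen growth, also had peaks 1 bp apart (chromosome 3, 10311104 to 10311503 with SEP3Δtet3M-AG). HEC1, HEC3, RBE, NUB, ETT and YAB3 had peaks in both lists. DAD1, an enzyme of jasmonate synthesis in anthers, and ARF6 had a peak with SEP3Δtet3M-AG alone. KNU, which ends the floral meristem, the carpel and fruit regulators SPT and IND, and GNL, ROXY1 and VDD had one with SEP3Δtet-AGΔtet alone. The gene nearest to the peak was BGAL12 for GNL, ACR6 for ROXY1, SAUR19 for VDD and, in both lists, AT1G13410 for NUB. For the counts in 1 list only, 2 and 6, no difference from an equal split was detected (exact binomial p = 0.289). Nor was one detected from the split of all genes with a peak in 1 list only. At a limit of 1000 bp the list passed with SEP3Δtet3M-AG (16.3% against 6.59%, Fisher's exact adjusted p = 0.0476), and without low-gene windows it passed with SEP3Δtet-AGΔtet (28.6% against 15.4%, Fisher's exact adjusted p = 0.0412).

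Hormone genes and the comparison list of housekeeping and photosynthesis genes did not pass the test in either list. Of 18 hormone genes, YUC2, an enzyme of auxin synthesis, had a peak in both lists. The share of the list with a peak was 5.56% with SEP3Δtet3M-AG and 16.7% with SEP3Δtet-AGΔtet (Fisher's exact adjusted p = 0.894 and 1). Of 21 housekeeping and photosynthesis genes, RCA had a peak in both lists, and ACT7 and GAPC2 had one with SEP3Δtet-AGΔtet alone (4.76% and 14.3%, Fisher's exact adjusted p = 0.719 and 1). None of these 21 genes had a peak within 1000 bp in either list, which allows a share of up to 16.1% (exact interval).

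The 2 complexes shared most of the SEP3Δtet3M-AG peaks, as at AG, AP3, SUP and MYB21. Of its 1681 peaks, 1137 overlapped a SEP3Δtet-AGΔtet peak (67.6%, interval 65.3 to 69.9), where random placement gave a mean of 25.5 and at most 43. Of the 2277 SEP3Δtet-AGΔtet peaks, 1131 overlapped the other list (49.7%, interval 47.6 to 51.8), against a random mean of 25.4 and at most 42. These are 44.6 and 44.5 times the random mean, with the smallest p that the placements can give (permutation p = 0.001). Overlapping peaks were nearly concentric. The median distance between their midpoints was 8 bp, 966 of 1137 (85.0%) lay within 20 bp, and the median signed distance was 0 bp. Across all protein-coding genes, 3305 (12.0%) had a peak within 3000 bp with SEP3Δtet3M-AG and 4338 (15.8%) with SEP3Δtet-AGΔtet, of which 2375 had one in both lists.

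**Figure D2:**
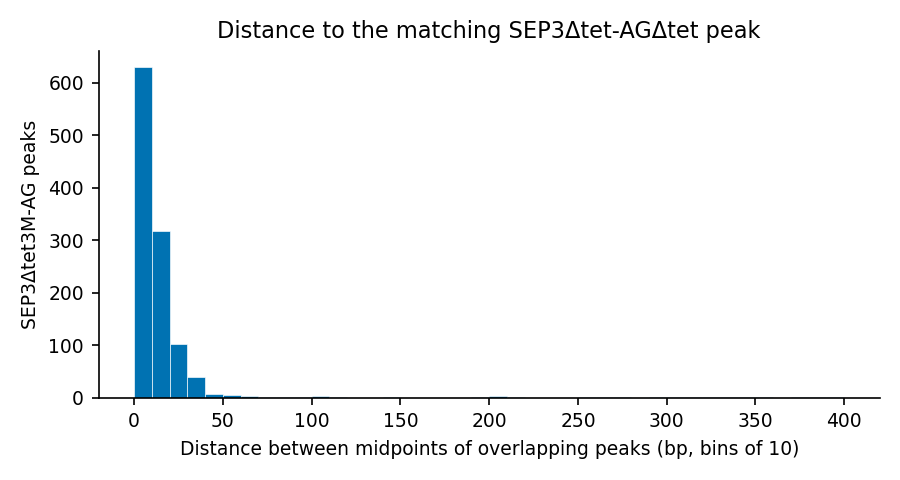
Distance in bp between the midpoints of overlapping peaks (horizontal axis, bins of 10 bp) against the number of SEP3Δtet3M-AG peaks (vertical axis), for the 1137 peaks of SEP3Δtet3M-AG that overlap a SEP3Δtet-AGΔtet peak. The median is 8 bp, and 97.8% lie within 100 bp.

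Peaks of both complexes lay next to genes more often than random positions did. The share outside a protein-coding gene but within 1000 bp of one was 30.2% with SEP3Δtet3M-AG (507 peaks, interval 28.0 to 32.4; random 20.5%; Fisher's exact adjusted p = 2.14e-18). It was 35.0% with SEP3Δtet-AGΔtet (798 peaks, interval 33.1 to 37.0; random 20.1%; Fisher's exact adjusted p = 2.34e-54). Inside genes lay 46.7% of SEP3Δtet-AGΔtet peaks (interval 44.6 to 48.8), below the random 54.4% (Fisher's exact adjusted p = 2.29e-12). For SEP3Δtet3M-AG the share was 52.2% (interval 49.8 to 54.6) against 54.1%, which did not pass (Fisher's exact p = 0.137). It did pass once low-gene windows were left out (54.8% against 62.3%, Fisher's exact p = 1.14e-08). Farther from genes lay 17.6% and 18.3% of the peaks, against 25.4% of random positions for each list (Fisher's exact p = 4.76e-13 and 8.74e-15). This last difference was lost without low-gene windows (Fisher's exact p = 0.159 and 0.803).

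Peaks found in 1 list only differed between the 2 lists in where they lay, a comparison chosen after the data were seen. Of the 544 peaks found with SEP3Δtet3M-AG only, 53.9% lay inside a gene, as at AP1, CAL and FT, against 41.9% of the 1146 found with SEP3Δtet-AGΔtet only. The difference was 12.0 percentage points (95% interval 6.90 to 17.0; Fisher's exact adjusted p = 1.38e-05). Next to a gene lay 26.1% and 37.9% of them (Fisher's exact adjusted p = 1.38e-05). Shared peaks had 51.5% inside and 32.1% next to a gene in the SEP3Δtet3M-AG list. Within the SEP3Δtet-AGΔtet list, peaks not shared lay inside genes less often than shared ones (41.9% against 51.5%, Fisher's exact adjusted p = 1.38e-05). Within the SEP3Δtet3M-AG list no difference inside genes was detected (53.9% against 51.5%, Fisher's exact p = 0.375). Its peaks that were not shared lay next to genes less often than shared ones (26.1% against 32.1%, Fisher's exact adjusted p = 0.0160) and more often in low-gene windows (10.8% against 6.51%, Fisher's exact adjusted p = 0.00482).

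**Figure D3:**
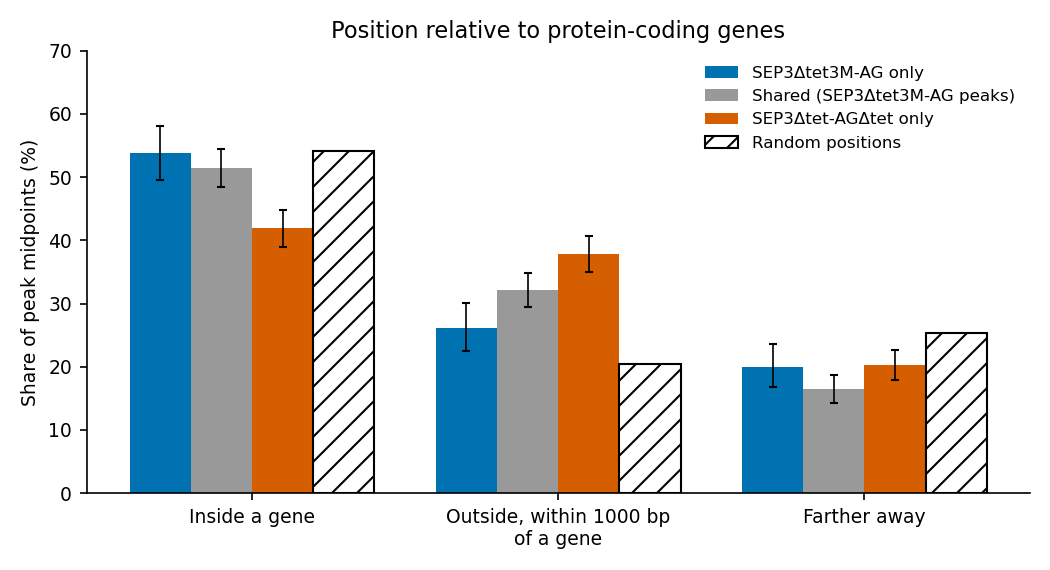
Share of peak midpoints, in percent, inside a protein-coding gene, outside but within 1000 bp of one, or farther away, for peaks found with SEP3Δtet3M-AG only (blue, 544), shared peaks of its list (grey, 1137) and peaks found with SEP3Δtet-AGΔtet only (orange, 1146). Error bars are exact 95% binomial intervals over peaks, and hatched bars are random positions drawn for the whole SEP3Δtet3M-AG list; inside genes the shares are 53.9%, 51.5% and 41.9%, against 54.1% of random positions.

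Gene-poor regions held fewer peaks than random placement put there. The 37 low-gene windows, of 238 in the genome, held 133 SEP3Δtet3M-AG peaks (7.91%, interval 6.67 to 9.31), against a mean of 15.6% of randomly placed peaks. They held 136 SEP3Δtet-AGΔtet peaks (5.97%, interval 5.04 to 7.03), against 15.5%. No random placement reached numbers so low (permutation p = 0.001 for each, the smallest possible). How well reads can be placed in these windows is unknown here, so the lower share need not come from binding. Among peaks found with 1 complex only, 10.8% of those of SEP3Δtet3M-AG lay in such windows and 5.41% of those of SEP3Δtet-AGΔtet (Fisher's exact adjusted p = 0.000239).

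The positions of peaks relative to genes rest on the fit of the peak files to the gene table. With the peaks as deposited, 52.2% (SEP3Δtet3M-AG) and 46.7% (SEP3Δtet-AGΔtet) of midpoints lay inside genes. Moving all peaks by 2000 bp or more gave 57.6 to 60.6% and 59.4 to 61.2%. With each chromosome split at its middle and both lists pooled, the share at no shift lay below the mean of the far shifts in 10 of 10 parts and below each far shift in 7.

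**Figure D4:**
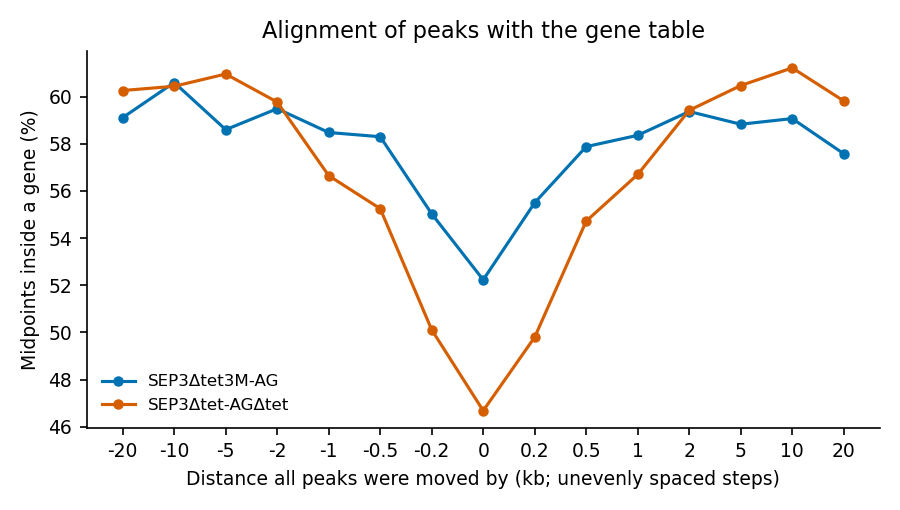
Share of peak midpoints inside protein-coding genes, in percent, after moving all peaks by the distance on the horizontal axis (kb, unevenly spaced steps; the vertical axis does not start at 0), for SEP3Δtet3M-AG (blue) and SEP3Δtet-AGΔtet (orange). Both curves are lowest at no shift, at 52.2% and 46.7%.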

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

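The comparison of peaks found with 1 complex only, and each test in the paragraph on its possible sources, were chosen after the result was seen. The tests on the MADS-box enrichment were likewise chosen after it was seen, and of these only the result of the placement matched for position was not yet known.

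Peaks found in 1 list only differed between the SEP3Δtet3M-AG and SEP3Δtet-AGΔtet lists by a test of the difference itself in 3 measures. Those of SEP3Δtet3M-AG lay inside genes more often by 12.0 percentage points, the difference in the share next to genes was -11.8 points, and that in low-gene windows was 5.44 points. Against random positions, the SEP3Δtet-AGΔtet peaks lay inside genes less often (41.9% against 54.3%, Fisher's exact p = 1.155e-15). For those of SEP3Δtet3M-AG no such difference was detected (53.9% against 55.5%, Fisher's exact p = 0.4976). Outside low-gene windows, 57.9% of the latter lay inside genes, against 62.3% of random positions drawn there for the whole list. With SEP3Δtet-AGΔtet the values there were 43.3% and 61.7%. Neither of these gaps was tested. Examples inside genes are AP1, CAL and FT with SEP3Δtet3M-AG and FUL with SEP3Δtet-AGΔtet. Background calls spread evenly along the chromosomes cannot be all of the SEP3Δtet3M-AG peaks, since 26.1% of those lay next to a gene against 19.4% of random positions (Fisher's exact p = 0.0003103). Background calls with another spread, such as one away from gene-poor regions, were not tested. Outside low-gene windows the share was 27.6%, against 22.3% of random positions drawn there for the whole list, a gap that was not tested. Background calls may be part of these peaks: 10.85% of them lay in low-gene windows, between the 6.51% of shared peaks and the 15.6% of random positions, and their share next to genes also lay between. Peaks of SEP3Δtet-AGΔtet that were not shared lay next to genes more often than its shared ones (37.9% against 32.2%, Fisher's exact p = 0.004924). This argues against background calls in the SEP3Δtet3M-AG list as the whole of the difference. It does not exclude them, since the value was known before the rule was set and the rule takes shared peaks as its standard. A difference in depth, caller threshold or GC content between the libraries was not tested, for want of reads, scores and sequence here, and with 1 library per complex a property of the complex stays open too.

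The enrichment of MADS-box genes was set against technical sources. Long genes or a general preference for gene flanks could raise the count, but none of 1000 placements of random peaks with the same numbers inside, next to and far from genes reached 17 list genes in either library. The highest had 12 for SEP3Δtet3M-AG and 13 for SEP3Δtet-AGΔtet (permutation p = 0.002 for each, the smallest that a two-sided test with 1000 placements can give). DNA carried over from the SEP3 and AG expression constructs could add peaks at those genes. SEP3 had no peak with SEP3Δtet3M-AG, and its 1 peak with SEP3Δtet-AGΔtet lay over 1000 bp outside the gene. No peak inside SEP3 is thus left for carried-over DNA to account for. It stays open for AG, where 1 of the 2 peaks of each list lay inside the gene. Leaving both genes out (higher Fisher's exact p = 3.558e-05) decides nothing, since removing 2 of 34 genes could not have ended the call. GC content and the presence of binding elements were not tested, and how the list was picked stays open. MADS-box genes outside it had a peak more often than other genes with SEP3Δtet-AGΔtet (Fisher's exact p = 0.01052). With SEP3Δtet3M-AG no such difference was detected (Fisher's exact p = 0.4513). Neither p was adjusted, unlike those of the fixed list, and both tests were set after the values were seen. A preference of the complexes for DNA near MADS-box genes is therefore 1 hypothesis among several.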

How the results depend on the processing

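Tests added after the data were seen are joint shifts, placement matched for position, shared peaks alone, peaks found with 1 complex alone, genes of every type, gene lists without low-gene windows, and every test of peaks found with 1 complex only. Of 97 alternatives to the values that answer a comparison, 81 were called the same. They kept their direction and their side of the threshold or, for peak numbers, stayed within 1.5 times. Many of the 81 are gene-list tests that passed in neither setting, and the share inside genes cannot change with the flank. The count therefore says little about results that passed. The 81 include each alternative run for the overlap of the lists, the share next to genes, low-gene windows and the location of peaks found with 1 complex only. Shared peaks stayed between 66.2 and 68.7% of SEP3Δtet3M-AG peaks and between 48.8 and 49.7% of SEP3Δtet-AGΔtet peaks. MADS-box genes passed in both lists under 5 alternatives, with 38.2% (shared peaks alone) to 50% of them having a peak. They did not pass with peaks found with 1 complex alone, set against placement matched for position: 14.7% had such a peak in each list, against a random 4.52% for SEP3Δtet3M-AG and 9.04% for SEP3Δtet-AGΔtet (adjusted permutation p = 0.25 and 1). Under the same setting flowering-time genes did not pass with SEP3Δtet-AGΔtet (31.2% against a random 8.46%, adjusted permutation p = 0.25), and 9.52% of housekeeping and photosynthesis genes stood above the random 8.06%. This setting leaves fewer peaks to test.

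Without low-gene windows, SEP3Δtet3M-AG peaks passed as fewer inside genes (54.8%), the share farther away no longer passed for SEP3Δtet3M-AG (14.0%) and turned for SEP3Δtet-AGΔtet (15.8% against 15.6%), and flower and meristem genes passed with SEP3Δtet-AGΔtet (28.6%, Fisher's exact adjusted p = 0.0412). With genes of every type the same 3 location values were 55.7%, 10.3% and 12.0%. At 1000 bp, flower and meristem genes passed with SEP3Δtet3M-AG (16.3%), and flowering-time genes no longer passed with SEP3Δtet-AGΔtet (12.5%). With shared peaks alone, flowering-time genes did not pass with SEP3Δtet-AGΔtet either (25% against 8.37%, Fisher's exact adjusted p = 0.0989), and hormone genes fell below other genes (5.56%). Under random placement, 14.3% of housekeeping and photosynthesis genes stood above the random 14.1%. The cause was not tested in any of these. Of 79 counts of peaks at single genes, 33 fell by over 1.5 times or to 0 at 1000 bp, where fewer peaks can be counted.

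No paired analysis was possible because each complex has 1 library, and for the same reason no replicate was left out. The stricter part of each list, the CArG box and 6-mer alternatives, shuffled windows and the GC-matched background were not run, and the effect of depth is unknown.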

Other observations

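The gene families, the microRNA genes, the neighbouring peaks and the genes named here were chosen after the data were seen, as were all tests in this part.

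Of 28 gene families defined by their names, MADS-box genes were the only one past adjustment over 56 Fisher's exact tests, in both lists. Of 98 such genes, which include members of the fixed list, 24 had a peak within 3000 bp with SEP3Δtet3M-AG (24.5%, interval 16.4 to 34.2; Fisher's exact adjusted p = 0.0148) and 34 with SEP3Δtet-AGΔtet (34.7%, interval 25.4 to 45.0; adjusted p = 0.000243). With SEP3Δtet-AGΔtet, NAC genes (26%), AP2/ERF genes (29.6%) and cytochrome P450 genes (21.8%) had the next smallest p and did not pass (Fisher's exact adjusted p = 0.122, 0.122 and 0.166). Among all protein-coding genes, the cold-response gene DREB1A and AT4G17370 were the only ones with 3 or more peaks within 3000 bp in both lists.

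The name family holds 67 MADS-box genes outside the fixed list, many from the less studied type I branch. With SEP3Δtet-AGΔtet, 19 of them had a peak (28.4%, interval 18.0 to 40.7), against 15.8% of other genes (Fisher's exact p = 0.01052, not adjusted). With SEP3Δtet3M-AG, 10 had one (14.9%, interval 7.396 to 25.7), against 12.0% (Fisher's exact p = 0.4513). By the rule of these tests, a preference limited to the picked genes fails with SEP3Δtet-AGΔtet and holds with SEP3Δtet3M-AG. The values had been seen before the tests were set, so the tests do not decide the question. In both lists the upper limit lies below the 50% of the fixed list. AGL28, AGL30 and AGL31 are among the 10 genes with a peak in both lists, and PHE1, AGL79 and AGL103 are among the 9 with a peak with SEP3Δtet-AGΔtet only. None had a peak with SEP3Δtet3M-AG only. The split of 0 against 9 is uneven by itself (exact binomial p = 0.00391), but does not pass against the split of all genes with a peak in 1 list only, 67.9% of which fall to the longer SEP3Δtet-AGΔtet list (exact binomial p = 0.0661). Neighbouring family members can share a peak.

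MicroRNA genes that act in the timing of flowering were looked at beside the flowering-time list. MIR156 and MIR157 genes, which repress SPL genes, had a peak within 3000 bp in 5 of 14 cases in each list. MIR156a, MIR156e, MIR157a and MIR157c were common to both. Random placement gave means of 1.17 and 1.56 (permutation p = 0.003 and 0.009). Over 11 families and 22 tests the adjusted permutation p was 0.066 and 0.099, so chance may be enough to give these counts. The count was not particular to MIR156 and MIR157. MIR169 genes, another family tested, had a peak in 5 of 14 cases with SEP3Δtet3M-AG and 6 of 14 with SEP3Δtet-AGΔtet. These did not pass either (permutation p = 0.034 and 0.026, adjusted p = 0.187 for each). None of 5 MIR172 genes had a peak in either list, where random placement gave means of only 0.364 (SEP3Δtet3M-AG) and 0.564 (SEP3Δtet-AGΔtet). All microRNA genes together had 25 and 37 of 326 with a peak, close to the random means of 27 and 37.2.

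Neighbouring peaks lay close together slightly more often than random in the SEP3Δtet-AGΔtet list. It held 151 pairs of neighbouring midpoints within 3000 bp against a random mean of 127 (permutation p = 0.017, and 0.036 with placement matched for position). Within 1000 bp it held 55 against 43.0 (permutation p = 0.048, and 0.107 matched). The SEP3Δtet3M-AG list held 74 against 69.4 and 29 against 23.3 (permutation p = 0.315 and 0.123). These p-values are not adjusted, and the difference between the lists was not tested.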
